A study of Rattus norvegicus with 16 samples.

How the data were processed

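RNA from 16 samples of primary rat microglia, in 4 groups of 4 given by the sample titles, was extracted with a column kit, and libraries were made by a sequencing company, per the labels' protocols. The authors deposited estimated counts per gene, as RSEM gives them, and TPM values per gene, 1 column per library. The submitters' processing notes list cutadapt 1.8.1, STAR 2.7.10b and RSEM 1.3.1, without role or order, and name the mouse build mm10, while all 30560 identifiers have the Ensembl rat prefix. The rat annotation is not given in the sources used here. If reads were assigned with an annotation other than the one the identifiers come from, counts of single genes would be affected; this could not be checked from the values.

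The deposited expected counts (3.24% of values not whole, by a tolerance of 0.005) were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 11902. All 16 libraries were fitted together with group means, TMM scaling and the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 12 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. SEs are the absolute log2 fold change divided by the square root of F. Comparisons were LPS against Control, ApoA-I against Control, LPS with ApoA-I against LPS, LPS with ApoA-I against ApoA-I, and the interaction. The 5 comparisons, their gene-level test and the alternatives not named below as chosen later were fixed before the data were examined; several tests of explanations were not.

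Of the planned analyses, the tests of 41 gene lists and the rule for naming genes could not be applied, because the counts are listed by Ensembl identifier and the name table used here (RefSeq, assembly GRCr8) gives an Ensembl identifier for 0 of its 47357 genes, so no identifier could be looked up. Instead 4 identifiers are printed: the largest increase and the largest decrease in LPS against Control and in LPS with ApoA-I against LPS, among genes with an adjusted p under 0.05, at least 5 mean CPM in the higher group, groups that do not overlap, and outside the 8 genes that varied together. This keeps the planned rule's conditions apart from the gene symbol, but the choice of 1 gene per direction in these 2 comparisons was made after values had been seen. The 8 genes were also defined after values had been seen, as genes of at least 1000 mean CPM whose deviations from their group means correlated above 0.95 with those of the most abundant gene.

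Positions along the LPS response are projections of log2 CPM (prior count 2) on the difference between the LPS mean and the mean of the 8 libraries without LPS, over genes called in LPS against Control, rescaled to the Control and LPS means. Positions were first tested on this scale (two-sided exact permutation p = 0.0286 for LPS with ApoA-I against LPS and 0.143 for ApoA-I against Control). As it is made with the labels compared, they were tested again, after these values had been seen, on the difference between all 8 libraries with LPS and all 8 without, over the 8625 genes called between these. Genes LPS raised by more than 4 log2 units, with at least 100 CPM in LPS libraries, were counted as higher on average in ApoA-I than in Control libraries in 3 ways, each chosen after values had been seen: 51 of 55 when chosen against the same Control libraries, 82.8% to 94.0% over 6 splits of the Control libraries, neither with a count expected without a change, and last 43 of 47 when chosen against all 8 libraries without LPS. Per-library values were compared by two-sided exact permutation tests over 70 arrangements. Folds against a group with no counts use a floor of 3 counts over the group; floors cover counting error only. Pairs of replicates differed by more than counting noise (chi-square per degree of freedom 3.14 to 95.8 over 24 pairs), so no library was treated as the same library sequenced again. This does not show that the replicates were separate cultures or animals.

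The tests were tried on simulated data, drawn from the real mean levels, library sizes and dispersions of 11902 genes. In each of 5 draws, 200 genes with a mean of at least 5 CPM were changed. Recovery of lower genes, and the scaling when most genes change, were not tried. Of the draws, 3 were added after the results of the others had been seen, and values are the lowest and highest over the draws. For LPS against Control, 83.6% to 95.5% of 1.5-fold and 97.0% to 100% of 2-fold changes were recovered, with 6 to 18 false calls. For ApoA-I against Control the values were 86.6% to 92.5% and 98.5% to 100%, with 8 to 14 false calls. For LPS with ApoA-I against LPS they were 83.6% to 91.0% and 97.0% to 100%, with 2 to 11 false calls, and against ApoA-I 85.1% to 92.5% and 100% in every draw, with 2 to 19 false calls. For the interaction they were 65.7% to 76.1% and 92.5% to 97.0%, with 7 to 10 false calls. With 0.5 of the response kept in the simulation, the slope came out at 0.490 to 0.498.

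Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2's size factors in edgeR, no filter on counts, a filter of 1 CPM in 4 libraries, the replicate number as a block, only the 8 libraries compared, limma on log2(TPM + 1) and log2(TPM + 0.1) of the authors' TPM values, all genes with a TPM above 0, and each library left out in turn. Chosen after seeing the data were fits with library totals only, without the 8 abundant genes, and with their log2 share as a covariate, and, for the share of genes moved back, other scalings and libraries outside the LPS group left out.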

Results

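Transcripts were measured by bulk RNA sequencing in primary rat microglia, the resident macrophages of the brain, cultured to day 12 in vitro. Lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates Toll-like receptor signalling, was given at 100 ng/ml for 20 hours. Apolipoprotein A-I (ApoA-I), the main protein of high-density lipoprotein, was added to the medium at 100 ug/ml. The 16 libraries fell into 4 groups of 4: Control, ApoA-I, LPS, and LPS with ApoA-I. Total estimated counts ranged from 12304916 to 17262383 per library. Of 30560 genes listed, 11902 had enough counts to be tested. The labels do not say whether the replicates were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The genes are listed by identifier without names, so results are given for groups of genes defined by their response, with 4 identifiers as examples.

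The first principal component of log2 CPM (counts scaled to the effective library size), with 78.9% of the variance, separated libraries with LPS from those without. The second, with 7.70%, separated LPS with ApoA-I from LPS alone. Each library was also placed along the LPS response, on a scale where the Control mean is 0 and the LPS mean is 1. Libraries with LPS and ApoA-I lay at 0.695 ± 0.0159 (SD, n = 4). Because the scale was made with the LPS libraries, it was also made with 2 of them at a time; over the 6 such splits the other 2 lay at 0.974 or higher, and every library with LPS and ApoA-I at 0.708 or lower. On a scale made from all 8 libraries with LPS against all 8 without, LPS with ApoA-I differed from LPS by -0.274 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows; 0.0762 after Benjamini-Hochberg adjustment over 16 such comparisons). ApoA-I libraries without LPS lay at 0.0289 ± 0.0281 (SD, n = 4) on the first scale; on the last, their difference from Control was 0.0348 and did not pass the test (two-sided exact permutation p = 0.171; adjusted 0.229).

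**Figure D1:**
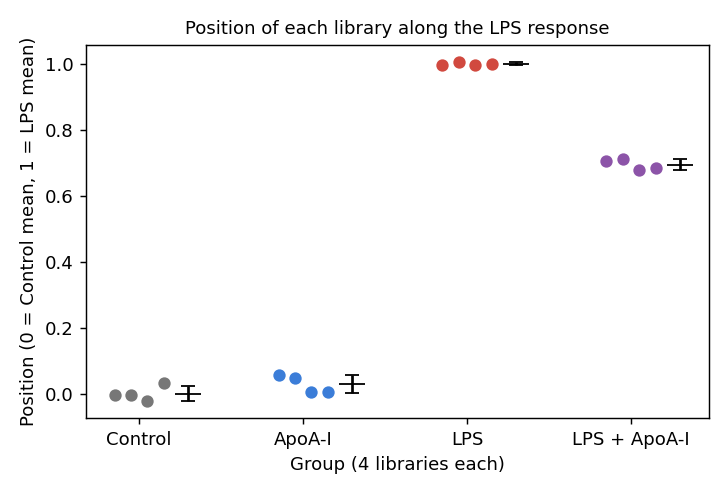
Position of each of the 16 libraries (points) along the LPS response, with the group mean and SD beside them (n = 4); the y axis has no unit and is set to 0 at the Control mean and 1 at the LPS mean. Libraries with LPS and ApoA-I lie between 0.677 and 0.710.

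LPS against Control asked which transcripts respond to LPS. LPS changed 8896 of the 11902 tested genes (74.7%), with 4326 higher and 4570 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test. By more than 1 log2 unit, 1332 genes rose and 2253 fell, and by more than 4 log2 units 203 rose and 284 fell. The 1332 genes raised by more than 1 log2 unit held 8.81% ± 0.587 of all counts in Control and 30.6% ± 1.34 in LPS libraries (SD, n = 4 each). The 2253 genes lowered by more than 1 log2 unit went from 14.6% ± 0.543 to 2.92% ± 0.178 of counts (SD, n = 4 each). Among the 92 most abundant genes by mean CPM over all 16 libraries, leaving aside 8 that varied within groups, 57 rose and 27 fell. The levels with LPS thus helped to choose these genes. ENSRNOG00000008478 had no counts in the 4 Control libraries and 230 ± 26.4 CPM in LPS libraries (SD, n = 4), at least 4960-fold higher against a floor of 3 counts over the group. ENSRNOG00000007574 had 14.1 ± 5.30 CPM in Control (SD, n = 4) and no counts in LPS libraries, at least 223-fold lower against the same floor.

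The balance of higher and lower genes depended on how libraries were scaled. With TMM scaling 48.6% of the called genes were higher in LPS than in Control, against 25.5% when only library totals were used and 23.6% on log2(TPM + 1). The median log2 change of all genes was -0.04 with TMM, -0.42 with library totals and -0.37 on log2(TPM + 1), so directions of small changes are relative to the scaling. For LPS with ApoA-I against LPS, the share of higher genes was 51.4%, 71.8% and 69.9% in the same order, with median changes of 0.03, 0.18 and 0.13. For LPS with ApoA-I against ApoA-I, the shares were 49.8%, 26.7% and 22.4%, with median changes of -0.01, -0.30 and -0.30. For ApoA-I against Control, the shares were 58.5%, 83.1% and 81.6%. For the interaction, the shares of positive values were 50.7%, 65.1% and 60.4%, with medians of 0.04, 0.13 and 0.07.

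**Figure D2:**
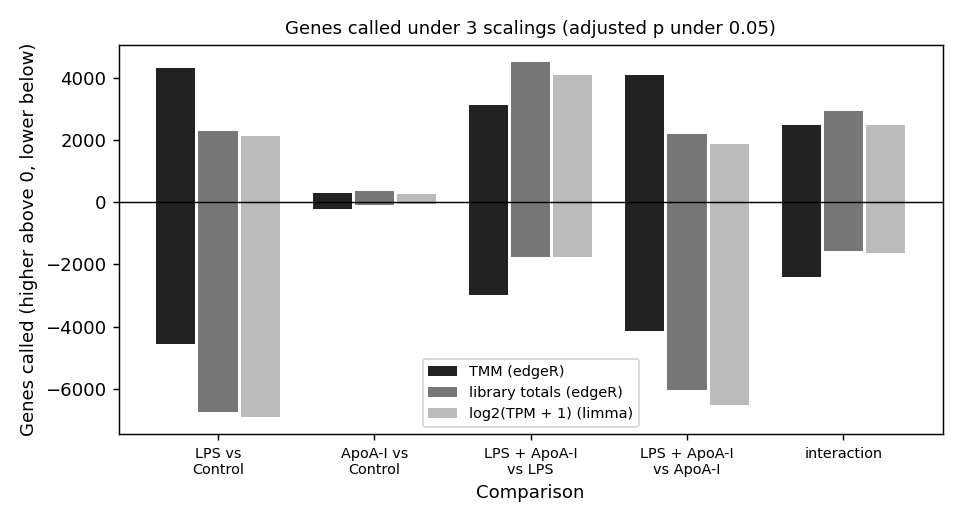
Number of genes called higher (bars above 0) and lower (bars below 0) in each of the 5 comparisons under 3 scalings; for the interaction, higher means a positive value. For LPS against Control, 4326 genes were higher with TMM, 2308 with library totals and 2134 on log2(TPM + 1).

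LPS with ApoA-I against LPS asked what ApoA-I does in LPS-treated cells. It changed 6114 genes (51.4% of those tested), with 3145 higher and 2969 lower, and 1228 of them by more than 1 log2 unit. The genes LPS had raised by more than 1 log2 unit fell from 30.6% ± 1.34 to 21.9% ± 0.795 of all counts (SD, n = 4 each), and those it had lowered rose from 2.92% ± 0.178 to 4.96% ± 0.238 (SD, n = 4 each). ENSRNOG00000002460, without counts in Control and ApoA-I libraries, fell from 42.6 ± 2.74 to 0.736 ± 0.419 CPM (SD, n = 4 each; log2 fold change -5.81, SE 0.22, edgeR adjusted p = 1.63e-12). ENSRNOG00000039976, which LPS lowered from 38.1 ± 2.92 to 0.249 ± 0.0849 CPM, rose to 6.35 ± 0.414 CPM with ApoA-I (SD, n = 4 each; log2 fold change 4.58, SE 0.29, edgeR adjusted p = 1.78e-11). ENSRNOG00000008478 fell to 10.3 ± 3.52 CPM (SD, n = 4; log2 fold change -4.49, SE 0.17, edgeR adjusted p = 7.22e-14). ENSRNOG00000007574 had 3 counts over the 4 libraries with LPS and ApoA-I and none with LPS alone, so no change was detectable at this depth.

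Most LPS-changed genes that ApoA-I changed moved back toward the Control level. Of the 1332 genes raised by LPS by more than 1 log2 unit, ApoA-I lowered 947 (71.1%), raised 75 further and left 310 without a call. Of the 2253 genes lowered by more than 1 log2 unit, it raised 1174 (52.1%), lowered 82 further and left 997 without a call. Both comparisons use the LPS libraries, so genes were also called with 2 LPS libraries and compared with the other 2. Over the 6 such splits, 43.5% ± 0.507 (SD over splits) of all LPS-called genes moved back and 7.45% ± 0.626 moved further. Across genes, which are not independent replicates, the 2 changes had a covariance of -0.653, against -0.0188 in simulated unchanged groups that share the LPS libraries. The simulation drew genes independently, so a shift of whole LPS libraries along the response was not in its covariance. The correlation of the 2 changes was -0.660. The simulated value of -0.531 is no reference for it, because the simulation held no LPS effect and its differences were noise only. If the call lists were independent, 1079 genes raised by LPS would be lowered by ApoA-I, against 2210 observed, and 1208 lowered by LPS would be raised, against 2148 observed. The lists are not independent, since the LPS libraries enter the 2 comparisons with opposite sign, so part of this excess is built in. Among the 3006 genes that LPS did not change by this test, ApoA-I in LPS-treated cells raised 551 and lowered 404.

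LPS with ApoA-I against ApoA-I gave the LPS response in the presence of ApoA-I, from libraries not used in LPS against Control. It held 8255 genes (69.4%), 4111 higher and 4144 lower, and 2690 of them changed by more than 1 log2 unit, against 3585 without ApoA-I. Both responses raised 3167 genes and lowered 3351, where independent lists would share 1494 and 1591. Over the 8896 genes called in LPS against Control, the response with ApoA-I had a least squares slope of 0.658 on the response without it (total least squares 0.704, Pearson's r = 0.905, Spearman's rho = 0.881, across genes, which are not independent replicates). The slopes of the 4 single libraries with LPS and ApoA-I had an SD of 0.0156. The fraction of the response that was kept varied between genes: for genes raised by more than 1 log2 unit the median was 0.640 (quartiles 0.416 and 0.811), and for genes lowered by more than 1 log2 unit 0.662 (quartiles 0.482 and 0.842).

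**Figure D3:**
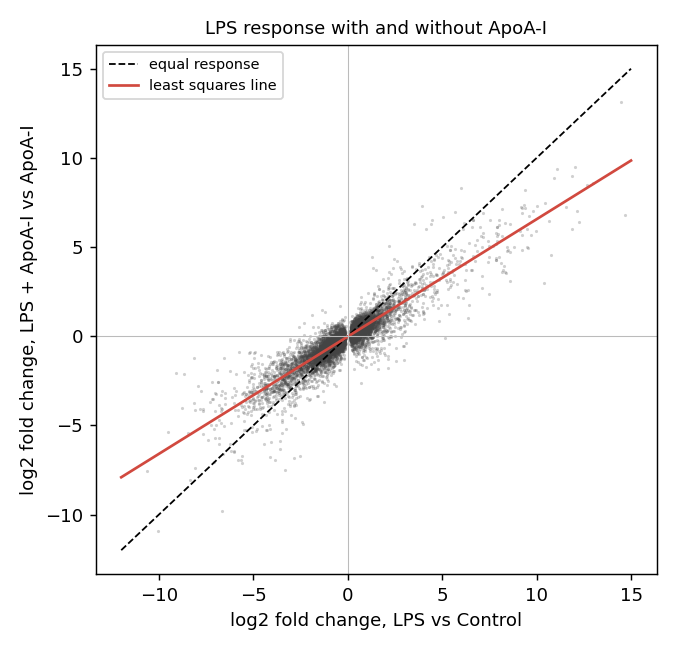
Log2 fold change of each of the 8896 genes called in LPS against Control (points), without ApoA-I on the x axis and with ApoA-I on the y axis; the dashed line marks equal responses and the solid line is the least squares fit. The fitted slope is 0.658; fitted values of genes without counts in a group depend on the prior count.

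The interaction tested whether the effect of ApoA-I differed between cells with and without LPS. It passed the test in 4880 genes, 2472 with a positive and 2408 with a negative value, and 1202 of them by more than 1 log2 unit. ENSRNOG00000039976 had 38.1 ± 2.92 CPM in Control and 37.9 ± 7.15 CPM in ApoA-I libraries (SD, n = 4 each), and an interaction of 4.59 log2 units (SE 0.32, edgeR adjusted p = 2.34e-10).

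ApoA-I against Control asked what ApoA-I does without LPS. It changed 508 genes (4.27%), 297 higher and 211 lower, of which 34 by more than 1 log2 unit. The median change was 0.36 log2 units among the higher and -0.33 among the lower genes. The number of calls was not stable: it was 94 when only the 8 libraries of these groups were fitted and 806 with DESeq2. Leaving out 1 library moved it by over 1.5 times in 5 cases, to 284 without Control 1, 325 without Control 2, 202 without Control 3, 775 without Control 4 and 186 without ApoA-I 1. With the labels of Control 4 and ApoA-I 4 exchanged it was 497. Across all tested genes the effects of ApoA-I with and without LPS had a Pearson's r of -0.0154 and a Spearman's rho of -0.0297. Few genes were called without LPS, so most differences on that side may be noise. A correlation this small then does not show that the effects were unrelated. Of the 297 genes ApoA-I raised without LPS, it raised 103 and lowered 110 in LPS-treated cells, where independent lists would share 78.5 and 74.1. Of the 211 it lowered, it lowered 91 and raised 62, against 52.6 and 55.8.

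Within groups, 8 of the 102 most abundant genes (1000 CPM or more on average) varied together, with a correlation of at least 0.980 to the most abundant one. They held from 1.61% to 12.8% of the counts of a library. The mean share was 7.87% ± 3.21 in Control, 3.91% ± 3.71 in ApoA-I, 8.74% ± 4.50 in LPS and 9.71% ± 2.48 in LPS with ApoA-I libraries (SD, n = 4 each). Fitting the log2 share as a covariate gave 224 calls in ApoA-I against Control, 207 of them among the 508 genes called without it.

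**Figure D4:**
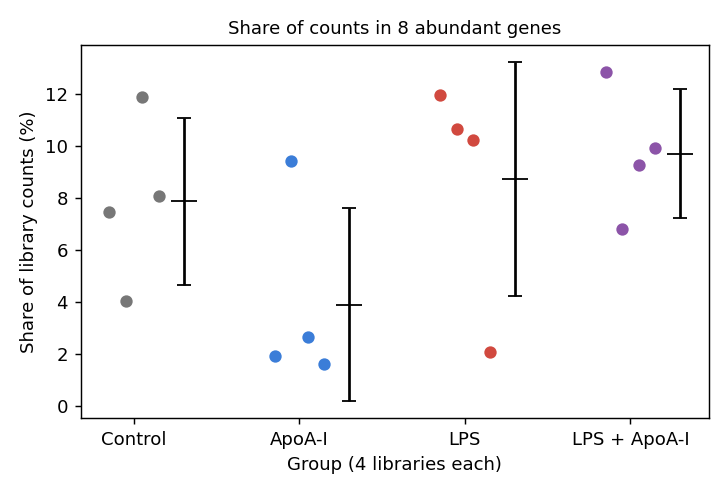
Share of each library's counts (percent, y axis) in 8 abundant genes that varied together, for the 16 libraries (points), with the group mean and SD beside them (n = 4). ApoA-I 2 lies at 9.43%, while the other ApoA-I libraries lie between 1.61% and 2.66%.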

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

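The tests of reduced LPS exposure, shared LPS libraries, shared reads, treatment effects on the 8 genes, carried-over reads and trace LPS activity were chosen after the results were seen.

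Other splits of the samples were used to ask whether chance could give as many calls. With 35 splits, 1 is the fewest that can reach the real count. Every other split puts libraries of both groups on each side, so a large group effect becomes spread and leaves few calls. The low counts of other splits therefore do not show how many calls would arise without an effect. For LPS against Control, 1 of 35 splits, the real one, gave 8896 calls, and the highest other gave 0. For LPS with ApoA-I against LPS, 1 of 35 gave 6114 and the highest other gave 1. For LPS with ApoA-I against ApoA-I, 1 of 35 gave 8255 and the highest other gave 0. For ApoA-I against Control, 1 of 35 gave 508, but the split that exchanged Control 4 and ApoA-I 4 gave 497, close to the real count. The count rose to 775 without Control 4 and to 706 without ApoA-I 4. An exchange of these 2 labels is not excluded by these counts, and what the 508 calls compare rests on the labels. For the interaction, the labels of all 16 libraries were shuffled. This does not keep the LPS effect in place, so these counts cannot say how many interaction calls chance would give. Of 100 drawn splits, 3 gave 4880 or more, the real one included, and the highest other gave 6792. In the other 2, 7 of the 8 LPS-treated libraries lay on one side of the contrast. Of the 10 drawn splits with 6 on one side, 1 gave 4405 calls and the others gave 0.

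The effect of ApoA-I differed with and without LPS in 4880 genes by the interaction test, among them ENSRNOG00000039976 with 4.59 log2 units. ENSRNOG00000008478 had a fitted interaction of -7.90, which depends on 5 counts in the library ApoA-I 2 and on the prior count. Without that library the gene has no counts in Control and ApoA-I libraries, so edgeR cannot test the interaction (fitted value -4.49); under the other 27 alternatives the adjusted p ranged from 2.75e-10 to 0.0233. With ApoA-I, more LPS-changed genes moved back toward the Control level than further from it. Noise of single LPS libraries, which both comparisons use, does not account for this. Genes moved back outnumbered genes moved further by at least 5.31 times in each of the 6 splits. The scaling does not account for it either, with a lowest ratio of 5.33 over 3 other scalings. A deviation common to all 4 LPS libraries would stay on both sides of a split, so the splits cannot exclude it. Lower effective LPS exposure with steady dose responses, as the only effect of ApoA-I, would leave few genes above both or below both of the Control and LPS levels. Such genes were 16.3% of those tested, and 12.97% in the scaling that gave the fewest, counting changes of any size. The bound of 5% was set after the results were seen. With more than 1 log2 unit from both the shares were 1.37% and 0.588%, under that bound, so the argument rests mostly on smaller changes. Both calls use the same 4 libraries with LPS and ApoA-I. A deviation common to these libraries would also place genes beyond both levels, so the shares argue against this explanation only if there was none. Lower exposure as part of the effect may account for the genes that moved back and cannot be told apart from an action of ApoA-I on the cells: 3.68% of genes changed by more than 1 log2 unit lay beyond the LPS level, which both allow.

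The share of counts in 8 abundant genes was 9.43% in ApoA-I 2, far from the other ApoA-I libraries. Leaving the 8 genes out moved the counts of calls by at most 1.06 times, but it shifted the scaling of no library by more than 0.02 log2 units and so decides nothing about their part in the calls. With their log2 share as a covariate the calls were 8956 for LPS against Control, 6150 for LPS with ApoA-I against LPS, 7371 for LPS with ApoA-I against ApoA-I and 4222 for the interaction, but 224 in place of 508 for ApoA-I against Control, where their part stays open. Of their values, 95.3% were not whole numbers, against 6.94% in other tested genes, which is consistent with reads divided between near-identical gene copies and may account for their moving together, though not for the difference between libraries; their single counts are uncertain. An effect of the treatments cannot be told apart with 4 libraries per group (permutation p = 0.107 for the share of variance between groups).

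Of the 441 genes called both in ApoA-I against Control and in LPS against Control, 74.1% moved the same way. With split Control libraries the share was 65.0% on average over 6 splits, from 49.3% to 75.0%, so shared Control libraries cannot be told apart from a shared effect. Simulated unchanged groups that share Control libraries gave a covariance of 0.0162, against 0.0829 observed. Genes were drawn independently there, so a shift of Control libraries along the LPS response was not simulated. The higher observed value therefore does not decide between shared Control libraries and a shared effect. The correlations, 0.479 simulated and 0.226 observed, cannot be compared, because the simulation held no LPS effect and its differences were noise only. Reads carried over from LPS libraries are argued against for the 203 genes raised by both: 7 genes nearly silent in Control limit a carried-over level to 0.0610% of the LPS level, which reaches the excess of 0.493% of these genes (median excess 10.7% of the LPS level). Trace LPS activity in the protein, or an effect of ApoA-I of its own, may remain: neither the positions along the LPS response (two-sided exact permutation p = 0.171) nor the number of strongly LPS-induced genes higher in ApoA-I than in Control libraries, 43 of 47 chosen without regard to these 2 labels (p = 0.0857 over 70 arrangements; the last of 3 counts made), passed the test, so both stay open.

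Single libraries stood far from the other 3 of their group in 6 of 36 groups of values. Besides the share above, these were the total of LPS 3 (16386274 counts), the share of counts in LPS-raised genes in LPS with ApoA-I 2 (23.1%), the share in LPS-lowered genes in LPS 4 (3.19%), ENSRNOG00000008478 in ApoA-I 2 (0.354 CPM) and ENSRNOG00000002460 in LPS 2 (38.5 CPM). Chance would give about 1.8 if all values were independent and normally distributed, which they are not. The result for ENSRNOG00000008478 was fixed in advance, since ApoA-I 2 held all counts of its group, and the shares of counts depend on each other.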

How the results depend on the processing

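Fits with library totals only, without the 8 abundant genes or with their share as a covariate, and other scalings or left-out libraries for the share of genes moved back, were chosen after seeing the data. The counts of calls in LPS against Control (8602 to 9373), LPS with ApoA-I against LPS (5631 to 6340), LPS with ApoA-I against ApoA-I (7371 to 8509) and the interaction (3813 to 4992) stayed within 1.5 times of the reported counts under every alternative run. ApoA-I against Control, with 508 calls, did not: it gave 806 with DESeq2, 310 on log2(TPM + 1), 238 on log2(TPM + 0.1), 100 with all genes with a TPM above 0, 94 with only the 8 libraries, 224 with the share of the 8 genes as a covariate, and 186 to 775 with 1 library left out. The cause was not tested. In the other comparisons the sets of called genes changed more than their counts with some scalings. With library totals, 7121 of the 8896 LPS against Control calls were made again. For LPS with ApoA-I the numbers were 4917 of 6114 against LPS and 6394 of 8255 against ApoA-I. For the interaction the number was 4055 of 4880. With DESeq2 the numbers were 8794, 5932, 8150 and 4726 in that order. The slope of the LPS response with on without ApoA-I (0.658) ranged from 0.641 to 0.666 with 1 library left out, and the correlation of the ApoA-I effects (-0.0154) from -0.0591 to 0.00593. The share of LPS-called genes moved back (43.5%) was 49.0% with unsplit LPS libraries, 52.9% for genes over 1 log2 unit, 45.3% with library totals, 42.5% on log2(TPM + 1), and 40.9% to 44.2% with 1 library outside the LPS group left out. No pairing by replicate number was seen: 3 of 24 same-numbered pairs correlated above 0.1 and 5 of 16 libraries correlated best with their own number. Correlations ran from -0.179 to 0.176 for same-numbered pairs and from -0.290 to 0.204 for others. A shared culture or animal is not excluded by this. With the replicate block the calls were 8850, 469, 6075, 8231 and 4808 for LPS against Control, ApoA-I against Control, LPS with ApoA-I against LPS, LPS with ApoA-I against ApoA-I and the interaction. The block gave a slope of 0.658 and a correlation of -0.0181. Of 572 alternative values of the 4 identifiers, 566 kept their side of the threshold, 1 lost it (ENSRNOG00000008478, interaction, where no counts remained without LPS) and 5 gained it (all ENSRNOG00000002460, interaction), and no called value changed sign. ENSRNOG00000002460 has no counts without LPS, so edgeR could not test its interaction (adjusted p = 1), while DESeq2 (0.000231), limma-voom (1.77e-05) and the fits on log2(TPM + 1) (2.63e-11), log2(TPM + 0.1) (1.02e-07) and all genes with a TPM above 0 (1.78e-09) called it. The gene lists and named genes were not run under any alternative, because identifiers could not be matched to names here. Estimated counts of low genes limit the folds, which are bounds where a group has no counts.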

Other observations

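Some genes responded in ways that the comparisons above do not describe. In libraries with LPS and ApoA-I, 1935 of the 11902 tested genes differed from both Control and LPS in the same direction, 1050 above both and 885 below both, by edgeR's quasi-likelihood test at an adjusted p under 0.05. With a change of more than 1 log2 unit from both, 51 genes lay above and 112 below. On log2(TPM + 1) the numbers were 808 and 736, and 36 and 34 with more than 1 log2 unit. This count was made after the other results were seen. Both differences use the same 4 libraries with LPS and ApoA-I, so a deviation common to these would also add to it.

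The LPS response was called in the opposite direction in the presence of ApoA-I for 28 of the 1332 genes that LPS raised by more than 1 log2 unit and for 12 of the 2253 genes it lowered by as much. These counts were made with TMM scaling only, and the direction of small changes depends on the scaling. No number expected without a reversal was made.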
